A study of Mus musculus with 4 samples.

How the data were processed

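RNA from mouse regulatory T cells of strain C57BL/6NJ was sequenced in 4 libraries, which the labels number as biological replicates 1 to 4 of a single group. Regulatory T cells are CD4+ T cells that restrain immune responses and depend on the transcription factor Foxp3. Each library has its own biosample record, but all 4 share a single donor record, and the labels do not say whether the cells came from separate animals or cultures. The p-values of the per-gene test below therefore measure the spread between these samples, which may be partly technical. The exact sign-flip permutation p-values of the contrasts are 0.125 whenever all 4 differences share a sign, whatever their spread. Those of the gene lists set each list against random lists of genes in the same libraries. Age was labelled unknown and sex not collected. The assay is titled as total RNA sequencing, whereas the linked library protocol is named for poly(A)+ RNA; a CD4+ T cell differentiation protocol is also linked. The sample names inside the files carry the words activated and sorted and a time of 72 h, which the labels do not repeat.

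The authors deposited raw gene counts, as whole numbers of read pairs per gene with no normalization, made with featureCounts 1.4.6-p4 from STAR alignments, per the file headers. The header records paired counting with both ends mapped, the reverse strand setting (2), exons grouped by gene, and the GENCODE release M13 annotation; the labels name the mm10 assembly. Multimapping and overlapping reads were not counted, per the file headers, so genes with near-identical copies (the haemoglobin, histone, 7SL and Hspa1a/Hspa1b genes) are undercounted and their levels are uncertain. Reads on the antisense strand were kept apart by the strand setting. Quality trimming and alignment settings are not given in the sources used here. The plan made before the data were examined had assumed estimated counts with posterior means; the files hold raw counts, so counts were used without rounding and the planned posterior-mean alternatives could not be run. The deposited text notes were not used.

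Each file held 50600 genes. Gene names, biotypes and GC content came from the GENCODE M21 annotation, which matched 50376 gene identifiers; the other 224 held at most 0.0103% of the counts of any library. Coordinates are those of the deposited files. TPM was computed here from the deposited counts and the exon lengths in the same files, and CPM from the library totals. Levels are given as mean ± SD over 4 libraries. A gene was counted as expressed at 1 TPM or more in every library. The 46044354, 72147632, 94983494 and 32648138 counts of replicates 1 to 4 put a floor of 3 counts at 0.0652, 0.0416, 0.0316 and 0.0919 CPM; this floor covers counting error only. TPM of very short genes is unreliable: genes with an exon length under 200 bp held 0.0591% of counts but 2.99% of TPM.

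With 1 group there was no contrast between groups. Contrasts were made within a library, as the difference of log2(TPM + 1) between Foxp3 and Tbx21, Gata3 or Bcl6, and between the median of the Treg identity list and that of the Th1, Th2, Th17, Tfh and naive lists. They were tested by an exact two-sided sign-flip permutation test with Benjamini-Hochberg adjustment over each family of contrasts; with 4 libraries it gives no p under 0.125. Excess variation was tested in edgeR 4.0.16 (R 4.3.3): filterByExpr with a minimum count of 10, TMM scaling, an intercept-only design, the trended dispersion and a one-sided goodness-of-fit test per gene, adjusted over 13494 genes and called at an adjusted p under 0.05. Counts were also simulated for these 13494 genes at the trended dispersion. Changed genes had a mean of 5 CPM or more and a changed level in 1 library. The test recovered 8% of genes changed by 1.5-fold, 74% by 2-fold and 100% by 4-fold. It called 3 of 13294 unchanged genes, but all of these were drawn at the trend. Real genes may scatter about the trend, so the 3 calls do not give the false-call rate among real genes. The common coefficient of variation was 0.161 in the simulated counts, changed genes included, against 0.135 in the real data. Because the filter required counts in every library, the Y-linked genes were left out of this test.

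In all, 34 gene lists with 328 distinct genes were fixed before the data were examined. For the 28 lists with at least 3 members at a mean of 0.5 CPM, the mean deviation of log2 CPM (prior count 2) from each gene's mean was taken per library. Its range over libraries was compared with 10000 random lists of the same size, matched within 150 ranks of mean expression, and adjusted over the 28 lists. As a check, 0.30 (log2) was added in 1 library to the measured levels of lists of 12 random genes. These genes had a mean of 5 CPM or more. Of 20 such lists 19 were called, and 0 of 20 unshifted lists. Shifted and unshifted lists were adjusted together, and the many shifted lists made the adjustment less strict than over the 28 lists. The 19 calls may therefore overstate what would be recovered there. The unshifted lists were random genes, like those of the comparison, so they do not give the false-call rate of co-regulated lists. Lists with fewer members or lower counts were not checked. Genes are correlated, so the random-list percentile describes these libraries and does not generalise to others.

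Named genes followed a fixed rule: the lineage factors; up to 4 members per list with the highest level (2 for other cell types), list members with excess variation, and Treg identity members under 1 TPM; the 10 highest nuclear protein-coding genes; the 20 genes with the smallest adjusted p at a mean of 5 CPM or more; and Xist, Ddx3y, Uty, Kdm5d, Eif2s3y, Malat1, Neat1, Rn7sk, Rmrp and Rpph1. Some items that this rule names are not reported here. Other genes named below were chosen after their values were seen. The alternatives were other detection thresholds, FPKM, pseudocounts and units, list summaries, DESeq2 1.42.0 size factors and dispersion outliers, limma 3.58.1, other filters, and leaving out each replicate. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used for the other steps.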

Results

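Gene expression was measured in 4 libraries of mouse regulatory T cells, biological replicates 1 to 4 of a single group. Replicate 1 held 46044354 counts, replicate 2 held 72147632, replicate 3 held 94983494 and replicate 4 held 32648138. Between 13239 and 13351 genes reached 1 TPM in a library, and 12114 genes did so in all 4. The libraries correlated across genes with a Pearson r of 0.988 to 0.993 on log2(TPM + 1), where genes are not independent replicates. In a screen for a library deposited again under another label, for which the chi-square per gene would be near 1, it was 11.8 or more in every pair; this value grows with depth and does not rank the pairs.

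The first question was how the factor that defines the labelled cell type compared with those of other helper T cell lineages. Foxp3 stood at 463 ± 25.4 TPM (SD, n = 4), the highest of the 4 lineage factors reported in every library. Gata3, the Th2 factor, reached 40.3 ± 4.50 TPM, Tbx21, the Th1 factor, 7.91 ± 2.39 TPM, and Bcl6, the Tfh factor, 5.18 ± 0.559 TPM. Foxp3 (ENSMUSG00000039521.12) lies on chromosome X at 7579676 to 7595243 in mm10 and held 17358 to 58291 counts per library. On the log2(TPM + 1) scale, Foxp3 exceeded Gata3 by 3.50 ± 0.10, Tbx21 by 5.74 ± 0.41 and Bcl6 by 6.24 ± 0.08 (SD, n = 4). Each difference was above 0 in 4 of 4 libraries, with an exact sign-flip permutation p of 0.125 (two-sided) before and after adjustment, the smallest that 4 libraries allow. These are comparisons of different genes within a library, so they also carry differences in how well each transcript is captured.

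Genes of the regulatory T cell programme were abundant. Of the 17 members of the Treg identity list, 16 reached 1 TPM in every library and 9 exceeded 100 TPM in the mean. Il2ra, the alpha chain of the interleukin-2 receptor, stood at 1769 ± 120 TPM, the costimulatory receptors Tnfrsf4 and Tnfrsf18 at 1431 ± 38.4 and 1141 ± 60.3 TPM, and Izumo1r, which encodes folate receptor 4, at 739 ± 86.4 TPM. The exception was Itgae, the integrin chain CD103, at 0.921 ± 0.387 TPM. The 3 genes associated with thymus-derived regulatory T cells were lower but present in every library, with Gpr83 at 45.5 ± 8.17 TPM, Nrp1 at 36.6 ± 3.65 TPM and the Helios gene Ikzf2 at 12.97 ± 1.77 TPM. Suppressive effectors were uneven: 6 of 14 reached 1 TPM in every library. Ccr8 (597 ± 70.2 TPM), Tgfb1 (335 ± 10.2 TPM), the interleukin-35 subunit Ebi3 (230 ± 15.7 TPM) and Lag3 (67.8 ± 11.6 TPM) were high. Il12a, on the same list, stood at only 1.03 ± 0.505 TPM, and Il10 averaged 0.340 TPM with no counts in replicates 1 and 4.

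**Figure D1:**
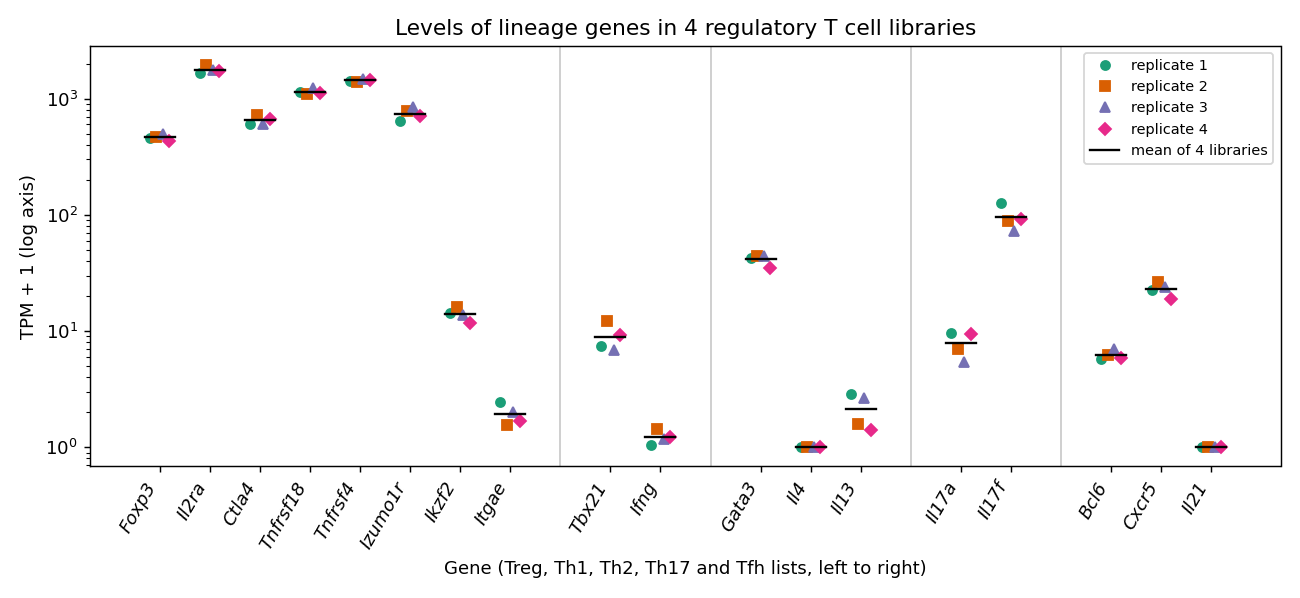
Levels of lineage genes as TPM + 1 on a log axis, with 1 point per replicate library and a line at the mean of the 4. Foxp3 lies between 433 and 495 TPM, above Gata3 (33.8 to 43.3 TPM), Tbx21 and Bcl6 in every library.

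The lists of other helper lineages had lower median levels than the Treg identity list, by amounts that depended on the unit and the members kept. The median of the Treg identity list exceeded that of the Th1 list by 3.53 ± 0.10, the Th2 list by 5.68 ± 0.63, the Th17 list by 3.74 ± 0.43, the Tfh list by 4.61 ± 0.10 and the naive and quiescent list by 1.14 ± 0.16 (log2, SD, n = 4). In TPM all 5 differences were above 0 in 4 of 4 libraries, each with an exact sign-flip permutation p of 0.125 (two-sided). The naive difference did not hold in CPM, without length correction: it was 0.01 ± 0.13, above 0 in 2 of 4 libraries (exact sign-flip permutation p = 1). With members under 1 TPM left out, the Th2, Th17 and Tfh differences were 1.53 ± 0.13, 2.63 ± 0.07 and 2.66 ± 0.11, so part of their size came from members under that level. In CPM the Th17 difference was 5.40 ± 0.20. Th17-associated genes included the chemokine receptor Ccr6 at 338 ± 22.8 TPM and the cytokine Il17f at 93.8 ± 23.2 TPM, and 7 of 11 members reached 1 TPM in every library, while Il17a stood at 6.83 ± 1.98 TPM and Il22 had no count. In the Th1 list 9 of 12 members reached 1 TPM in every library, led by Tnf at 184 ± 9.98 TPM and Runx3 at 85.8 ± 4.43 TPM, with Ifng at 0.223 TPM. In the Th2 list 4 of 9 did, led by Ccr4 at 214 ± 7.75 TPM and Il4ra at 148 ± 6.78 TPM, and Il4 had no count in any library. In the Tfh list 5 of 8 did, led by the inhibitory receptor Pdcd1 at 238 ± 3.73 TPM and by Cxcr5 at 21.8 ± 3.18 TPM. All 11 naive and quiescent T cell genes were expressed, among them the lymph node homing receptor Ccr7 at 631 ± 78.3 TPM and Tcf7 at 420 ± 12.04 TPM.

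Signalling and activation genes were expressed broadly. All 14 T cell receptor activation genes reached 1 TPM in every library, with Irf4 at 629 ± 28.4 TPM, Nr4a1 at 562 ± 18.8 TPM, Irf8 at 550 ± 25.3 TPM and Myc at 457 ± 16.8 TPM. All 10 interleukin-2 and STAT5 response genes did so, led by the cytokine Lta at 2731 ± 118 TPM and the feedback inhibitors Socs1 (407 ± 31.8 TPM) and Cish (398 ± 15.7 TPM). In the TGF-beta response list 8 of 9 did, led by Ski at 159 ± 2.75 TPM and Pmepa1 at 104 ± 6.56 TPM. In the retinoic acid and gut homing list 6 of 9 did, with Itgb7 at 181 ± 13.01 TPM and no count of Ccr9. Coinhibitory receptors were expressed in 6 of 8 cases, with Ctla4 at 649 ± 57.2 TPM and Cd274 at 116 ± 13.7 TPM. Chemokine receptors were expressed in 8 of 12 cases, with Ccr7, Ccr8, Ccr6 and Ccr4 above 200 TPM.

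Proliferation and biosynthesis genes were high in every library. All 23 proliferation genes were expressed, with a median of 206 TPM, including the replication factors Pcna (430 ± 12.7 TPM) and Mcm6 (421 ± 25.9 TPM). All 15 glycolysis genes were expressed, with a median of 545 TPM, led by Ldha at 3637 ± 73.4 TPM and Pkm at 2405 ± 152 TPM. All 13 cholesterol biosynthesis genes were expressed, led by Srebf2 at 479 ± 11.1 TPM, and 9 of 10 mitochondrial oxidation genes, led by Atp5b at 1494 ± 26.0 TPM. All 9 hypoxia response genes were expressed, with a median of 63.3 TPM, as were all 7 p53 response genes, with a median of 76.0 TPM and the cell cycle inhibitor Cdkn1a at 517 ± 12.8 TPM. In the stress and immediate early list 6 of 8 members were expressed, with Junb at 1238 ± 74.3 TPM. Interferon response genes were mostly low, with 5 of 12 at 1 TPM in every library and a list median of 0.578 TPM, although Bst2 stood at 240 ± 19.0 TPM. The highest nuclear protein-coding genes were Eef1a1 (13790 ± 1498 TPM) and Rplp1 (10770 ± 1197 TPM), both of the translation machinery.

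Markers of other cell types were set beside those of T cells. All 14 pan T cell genes were expressed, among them Trac at 1138 ± 116 TPM, Cd2 at 949 ± 39.1 TPM and Cd4 at 557 TPM. None of 9 neutrophil genes reached 1 TPM in every library, and 7 had no count. The numbers were 1 of 6 for NK cells (Klrd1, 1.62 ± 0.654 TPM), 2 of 5 for gamma-delta and NKT cells (Tcrg-C2, 1.77 ± 0.819 TPM), 2 of 12 for monocytes and macrophages (Cd68, 7.45 ± 1.25 TPM), 1 of 11 for erythroid cells and platelets, and 2 of 7 for stromal and endothelial cells (Pecam1, 9.37 ± 0.343 TPM). The CD8 and cytotoxic list had 3 of 7, with Nkg7 at 96.3 ± 15.7 TPM and Cd8b1 at 14.4 ± 2.09 TPM, but Cd8a at 0.332 TPM. Of the 11 B cell genes 3 were expressed, with the immunoglobulin constant region genes Ighm at 318 ± 8.58 TPM and Igkc at 19.0 ± 5.33 TPM, while Ms4a1 lay below 0.01 TPM. Of the 10 dendritic cell genes 3 were expressed, with Cd74 at 548 ± 16.2 TPM and H2-Ab1 at 53.1 ± 17.5 TPM, while H2-Aa averaged 0.436 TPM.

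RNA classes were measured because the assay title and the library protocol name different RNA fractions. Ribosomal protein genes took 6.75 ± 0.415% of counts, mitochondrially encoded genes 1.01 ± 0.0495% and long non-coding RNA 0.80 ± 0.142% (SD, n = 4). Small RNA classes without a poly(A) tail held 0.00914 ± 0.00181% and the histone cluster genes 0.00501 ± 0.00163%. Among the fixed genes of RNA without a poly(A) tail, 2 of 8 reached 1 TPM in every library, Rn7sk and Rpph1, and 4 had no count. The long non-coding class, which includes Xist, was at 0.96%, 0.88%, 0.69% and 0.67% in replicates 1 to 4. Ribosomal RNA with Gm42418, a non-coding locus that carries ribosomal RNA sequence, held 0.296 ± 0.267%, an SD near the mean. It was at 0.685% in replicate 1, 0.241% in replicate 2, 0.170% in replicate 3 and 0.0879% in replicate 4. Multimapping reads were not counted, so this share may understate ribosomal RNA. Gm26917, beside Gm42418 on chromosome 17, was classed as long non-coding RNA and measured 832, 422, 405 and 293 TPM in replicates 1 to 4. As a share of TPM rather than counts, ribosomal protein genes took 13.5%, mitochondrially encoded genes 2.46%, long non-coding RNA 1.03% and ribosomal RNA with Gm42418 0.526%. The small RNA classes took 0.254% of TPM and the histone cluster genes 0.0263%, both above their shares of counts because TPM weights short genes, so these shares depend on the unit.

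The second question was which genes differed between replicates more than genes of the same abundance. By edgeR's goodness-of-fit test, 51 of 13494 genes did at an adjusted p under 0.05, and the common biological coefficient of variation was 0.135. Xist, the non-coding RNA that silences an X chromosome, stood at 312 and 331 TPM in replicates 1 and 2 and at 0.539 and 2.38 TPM in replicates 3 and 4. The Y-linked genes ran the other way, with Eif2s3y at 0.0830, 0.132, 49.3 and 67.7 TPM and Ddx3y at 0.0664, 0.0264, 26.1 and 31.2 TPM in replicates 1 to 4. The 4 Y-linked genes, Kdm5d and Uty among them, were called when genes were kept by a mean of 1 CPM, a filter chosen after seeing the data, under which 67 genes were called (largest edgeR adjusted p of the 4, 8.06e-110). X-linked Kdm6a measured 33.4, 43.9, 20.8 and 21.8 TPM (edgeR adjusted p = 8.56e-10) and Eif2s3x 71.98, 82.3, 44.8 and 49.97 TPM (edgeR adjusted p = 1.80e-05).

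Replicate 1 lay farthest from the mean for 32 of the 51 genes, higher in 16 and lower in 16. Gm42418 measured 11890 TPM in replicate 1 against 4335, 2980 and 1555 TPM in the others (edgeR adjusted p = 7.64e-38), and the nuclear RNA Malat1 131 against 55.2, 44.1 and 42.5 TPM (edgeR adjusted p = 1.34e-38). Rn7sk, the RNA of the 7SK particle, measured 92.9 against 14.4, 14.5 and 9.02 TPM (edgeR adjusted p = 2.47e-10), and Lars2, a mitochondrial tRNA synthetase, 422 against 254, 198 and 165 TPM. Lars2 fell across the libraries in the same order as Gm42418, so it is not read here as a mitochondrial change. Il17f was also highest in replicate 1, at 126 against 87.3, 71.0 and 90.7 TPM (edgeR adjusted p = 0.00133), as was the enkephalin precursor gene Penk, at 103 against 59.6, 50.5 and 52.0 TPM. The glucose transporter gene Slc2a3 was lowest there, at 28.3 against 54.1, 50.5 and 41.5 TPM (edgeR adjusted p = 1.84e-05), as was Bnip3, a hypoxia-induced mitophagy gene, at 94.6 against 178, 143 and 143 TPM (edgeR adjusted p = 6.73e-04). The MHC class II gene H2-Ab1 varied from 33 to 73.8 TPM and Tgm2 from 51.6 to 95.5 TPM, and Arhgap18 was low in replicate 3, at 2.31 TPM against 7.68, 11.3 and 10.2 TPM. The count of 51 was 17 without replicate 1, 23 without replicate 3 and 14 by limma.

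**Figure D2:**
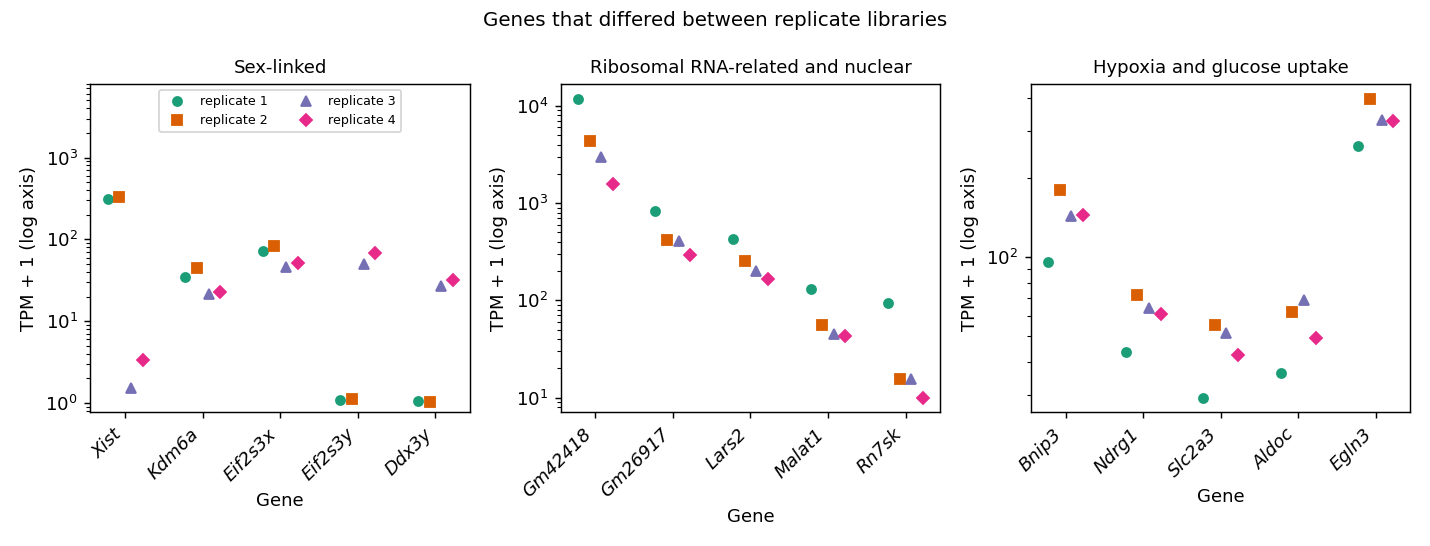
TPM + 1 on log axes for genes of 3 kinds, with 1 point per replicate library. Xist is at 312 and 331 TPM in replicates 1 and 2 and at most 2.38 TPM in replicates 3 and 4, Gm42418 and Rn7sk are highest in replicate 1, and Bnip3 and Slc2a3 are lowest there; Egln3 is shown as a hypoxia list member that did not pass the test.

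At the level of gene lists, 3 of 28 lists had a wider range between libraries than matched random lists at an adjusted p under 0.05. The Y-linked list ranged over 8.69 (log2; random-list permutation p = 0.0001, the smallest 10000 lists can give). The hypoxia response list ranged over 0.39, at -0.27 in replicate 1 and 0.09, 0.05 and 0.12 in the others (random-list permutation, adjusted p = 0.0439). In that list 7 of 9 members were lowest in replicate 1, and 2 members, Bnip3 and Ndrg1, varied beyond the trend over all genes and 5 when adjusted over the list alone. The interferon response list ranged over 0.71 on 5 members, at 0.44 in replicate 1 and -0.27, -0.14 and -0.03 in the others (random-list permutation, adjusted p = 0.0439). Of those 5 members 3 were highest in replicate 1: Isg15, at 22.1 against 6.23, 9.68 and 6.98 TPM, Irf7, at 4.30 TPM, and Usp18, at 2.80 TPM. No member was called over all genes while 1 was when adjusted over the list alone. Before adjustment, p was 0.0044 for the hypoxia list and 0.0047 for the interferon list (random-list permutation). Their adjusted values depend on the Y-linked list ranking first among the 28 lists. With that list left out of the adjustment, neither of these unadjusted values would pass 0.05. Over all genes, 1 member each of the Th17 (Il17f), retinoic acid (Tgm2), glycolysis (Slc2a3), dendritic cell (H2-Ab1) and non-polyadenylated RNA (Rn7sk) lists was called, and the same number in each when adjusted over the list alone. The Treg identity, thymus-associated, naive and p53 lists each had 1 call when adjusted over the list alone and 0 over all genes. Without its member of widest range, Isg15, the interferon list ranged over 0.43 and did not pass (random-list permutation, adjusted p = 0.416), a step chosen after seeing the data. The same step, without Adm, left the hypoxia range at 0.38 with p = 0.0039 against 0.0044 before adjustment, but an adjusted p of 0.0546 (random-list permutation). Without replicate 1 the ranges fell to 0.07 for hypoxia and 0.25 for interferon (random-list permutation, adjusted p = 0.688 and 0.491). Without replicate 2 neither list passed, but the ranges were still 0.39 and 0.57 (random-list permutation, adjusted p = 0.0518 and 0.137). After GC and length trends were removed neither passed, at 0.36 and 0.63 (random-list permutation, adjusted p = 0.0812 and 0.0994).

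**Figure D3:**
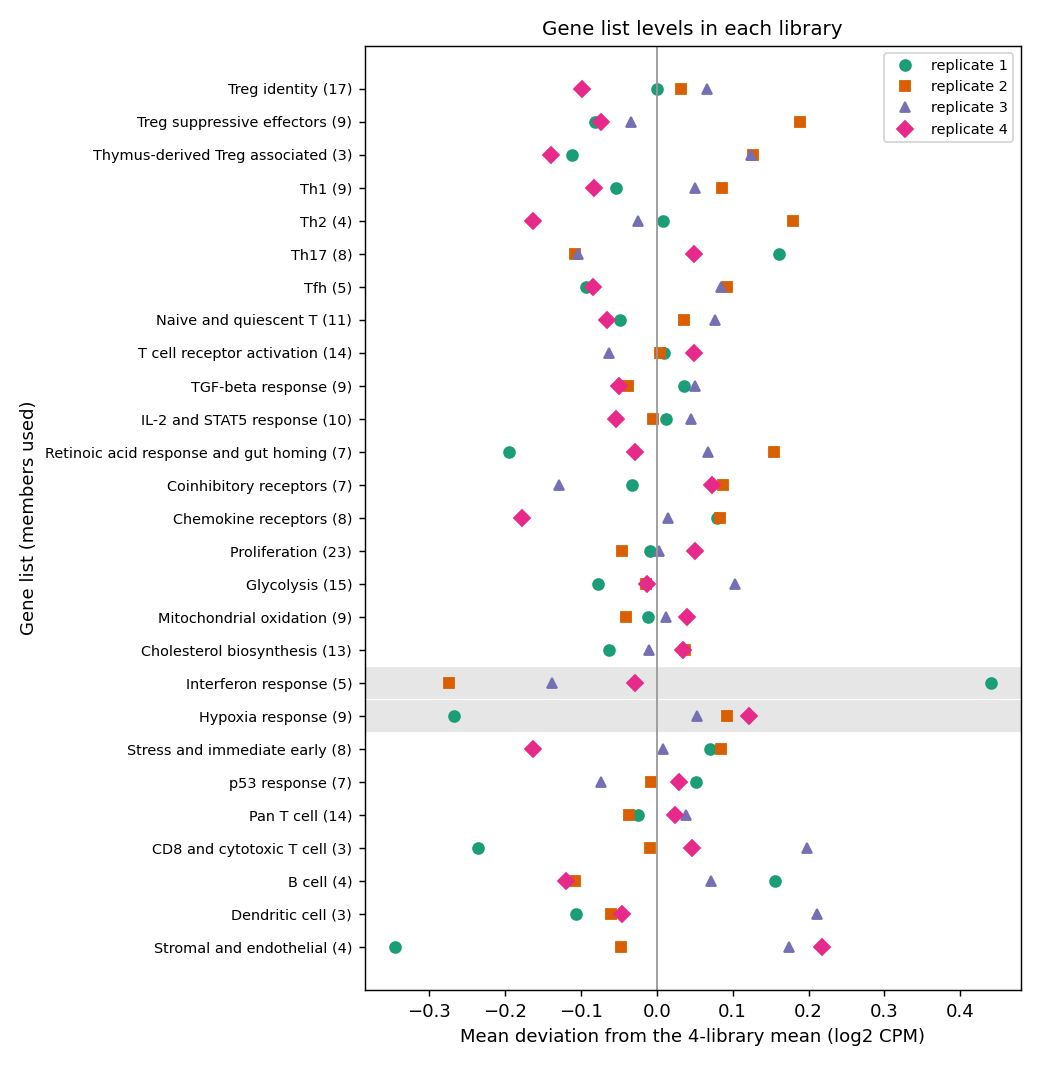
Mean deviation of each gene list from its mean over the 4 libraries (log2 CPM), with 1 point per replicate library, the members used in parentheses and shading for lists whose range passed the comparison with random lists. The hypoxia list is at -0.27 and the interferon list at 0.44 in replicate 1, and the Y-linked list, with a range of 8.69, is left out of the plot.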

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

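The values below were picked out because 1 library lay far from the other 3 by Dixon's criterion. Of 187 values examined, 16 were picked out, and chance alone picks out about 1 in 20. Except for the range after GC and length correction, whose bounds were set before it was computed, the tests of explanations and the bootstrap intervals were chosen after the results were seen.

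In replicate 1, Rn7sk was highest at 92.9 TPM and Malat1 at 131.5 TPM, whereas Nrp1 was lowest at 31.2 TPM and Rpl4 at 5043 TPM. In replicate 2, Ccr4 was highest at 225.9 TPM, Il24 at 3.89 TPM and Foxo1 at 69.5 TPM, whereas Cox4i1 was lowest at 610.6 TPM, Cd74 at 524.0 TPM and Rplp1 at 8989 TPM. In replicate 3, Myc was highest at 482.3 TPM and Pkm at 2631 TPM, whereas Rrm2 was lowest at 374.5 TPM. In replicate 4, Ldlrad4 was highest at 50.3 TPM, whereas Jun was lowest at 64.9 TPM and Neat1 at 29.7 TPM. Of these 16 genes, Rn7sk and Malat1 also varied beyond the trend in edgeR's test.

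Gm42418, Malat1 and Rn7sk were highest in replicate 1. A lower depth is argued against, because replicate 4, with the fewest counts, had the lowest share of ribosomal RNA and Gm42418, 0.0879%. A candidate explanation is a larger amount of RNA without a poly(A) tail in replicate 1: over 75 other genes of that kind, Rn7sk left out, the median deviation there was 0.43 (log2; 95% bootstrap interval over genes 0.28 to 0.58), against -0.19, 0.10 and -0.23 in replicates 2 to 4. The shares of these RNA classes had been seen before the test. The 75 genes were also higher in replicate 3 than in replicate 2, whereas the share of ribosomal RNA and Gm42418 was lower, at 0.170% against 0.241%. Another nuclear RNA, Neat1, which is not among the 75 genes, measured 32.3, 32.6, 32.5 and 29.7 TPM in replicates 1 to 4. The cause stays open. No biological explanation was tested, since the design gives none.

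The hypoxia list was lowest in replicate 1. A lower depth is argued against, because replicate 4 has fewer counts and its list level was higher by 0.39 (log2). After GC and length trends were removed, the range was 0.36 (log2) against 0.39 before, and replicate 1 minus the mean of the others was -0.34 (95% bootstrap interval over genes -0.47 to -0.20) against -0.36 (-0.50 to -0.20), which argues against those trends as the whole cause. The adjusted p nevertheless rose from 0.0439 to 0.0812: the unadjusted random-list permutation p moved only from 0.0044 to 0.0068, and the step to the adjusted value depends on the other lists. A difference in culture density or oxygen may be involved but was not tested, and it cannot be separated from whatever raised Gm42418 in the same library.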

How the results depend on the processing

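Alternatives were planned before the data were examined, except the mean CPM filter, the fit without Xist and Y-linked genes, the GC and length correction, the removal of short genes and of the widest list members, which were chosen after seeing the data. No contrast could pass 0.05, so only direction and size were compared. Treg identity minus naive was 0.01 ± 0.13 in CPM without length correction, above 0 in 2 of 4 libraries (exact sign-flip permutation p = 1), against 1.14 in TPM. The other contrasts stayed above 0 in every library used, with changes in size: Th2 was 1.53 with members under 1 TPM left out, 4.35 by list means, 6.62 with a pseudocount of 0.1 and 6.68 in CPM, against 5.68. Th17 and Tfh were 2.63 and 2.66 with members under 1 TPM left out, against 3.74 and 4.61. In CPM, Th17 was 5.40, Th1 4.23 against 3.53, Foxp3 minus Tbx21 6.37 against 5.74 and Foxp3 minus Bcl6 5.61 against 6.24. The 12114 expressed genes became 9726 at 5 TPM and 12995 at 0.5 TPM. The 51 variable genes became 14 by limma (all 14 shared), 48 by DESeq2 (47 shared), 38 with no filter (29 shared) and 67 with the mean CPM filter (46 shared); leaving out replicates gave 17 to 56, with 15 of the 51 called again without replicate 1 and 23 without replicate 3. The coefficient of variation was 0.260 with no filter, where many genes of low count enter. The 3 lists past the threshold became 6 with list medians, where Treg identity, thymus-associated and chemokine receptor lists joined, and 1, the Y-linked list, after GC and length correction or without the widest members (Adm and Isg15); leaving out replicates gave 1 to 3. With a mean of at least 10 CPM there were also 3: Th17, hypoxia and Y-linked. The interferon list had fewer than 3 members at that level, so it was not tested there. As shares of TPM, mitochondrial genes took 2.46%, ribosomal protein genes 13.5%, long non-coding RNA 1.03%, small RNA without a poly(A) tail 0.254% and histone genes 0.0263%, since TPM weights short genes. Leaving out 1 of 4 libraries cannot move a mean by 1 SD, so the named-gene means were bound to stay within it there. With genes under 200 bp left out, 124 named-gene means stayed within 1 SD and 15 moved further. With the mitochondrial, ribosomal RNA and non-polyadenylated classes left out, 119 stayed and 17 moved further. The causes of the other changes were not tested. Posterior-mean alternatives were not run, and TPM computed here replaced deposited TPM. Genes under the floor of 3 counts cannot be ranked.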

Other observations

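The tests in this part were chosen after the results were seen. Xist was at 94.3% and 100% of its highest level in replicates 1 and 2 and at 0.163% and 0.720% in replicates 3 and 4, whereas the mean of the 4 Y-linked genes was at 0.159% and 0.188% in replicates 1 and 2 and at 78.4% and 100% in replicates 3 and 4. If each library pooled cells of both sexes, Xist and the Y-linked genes would both be well above 0 in each, but in 4 of 4 libraries 1 of them was under 5% of its highest level. The explanation that all 4 libraries came from a single animal is also argued against, because Xist differed 599-fold in CPM between the highest and lowest library, although the labels give a single donor record. A candidate explanation is that the cells of different libraries came from animals of different sex; sex was not collected in the labels, so this stays a hypothesis, and no groups were formed from it. Il27ra on chromosome 8 divided the libraries in the same way, at 66.7, 68.9, 38.4 and 37.7 TPM, and the source of that difference was not tested.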
